A study of Mus musculus with 45 samples.

How the data were processed

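RNA-seq libraries of 45 pooled mouse samples in 22 groups were analysed from the processed files the authors deposited. RNA came from sorted T cells, sorted stromal cells, ILC2, adipocytes and whole fat, and libraries were made with a TruSeq kit, except those of stroma and ILC2, made with a Clontech kit, per the labels' protocols. Mice were 25 weeks old where the labels give an age; the spleen reporter Treg have none. Libraries were treated as separate pools of mice, as the labels name no animals shared between groups. P-values of single genes measure the spread between pools. Those of the overlap and permutation tests compare genes.

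The authors deposited a count table, which holds whole-number read counts for 27179 genes by Entrez identifier. Subread 1.6.2 with featureCounts, limma and the builds GRCm38 and mm10 are named in the submitters' processing notes; alignment settings, annotation and strand setting are not given in the sources used here. A set of 6 columns in that table matched no sample used here and was left out. The authors also deposited log2 FPKM values for each library, which were used only to check the columns: all 45 files correlated best with the count column of their own library. In 25 libraries the highest log2 FPKM value was shared with another library, and how these values were normalized is not given in the sources used here. Names came from the deposited files for 16534 identifiers and from a RefSeq table of GRCm38.p6 for 8784; 1861 had no name and took 0.383% to 4.994% of reads. Coordinates are from that table.

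Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit, glmQLFTest), with TMM factors, filterByExpr by group and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. There were 4 fits, over 19 T cell, 14 fat and adipocyte, 8 stromal and 4 ILC2 libraries, with group as the term. Positive log2 fold changes are higher in males, in VAT, or in the libraries labelled Blimp1-deficient. The SE is the log2 fold change divided by the square root of F. CPM are TMM-scaled, except for levels per library of Prdm1, Xist and Foxp3, marker sums and the test of ILC2 RNA, which use all counts with no such scaling. A fold against a group at 0 was computed against a floor of 3 counts over the group. It covers counting error only, so a fold given as 'at least' does not cover the spread between pools. Lists of genes, 38 in all, were tested two-sided with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison.

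Named genes and gene lists were chosen by rules fixed before the data were examined. For genes, the rule took the 6 most positive and 6 most negative called genes (3 in secondary comparisons) whose libraries did not overlap and whose higher group averaged at least 5 CPM, leaving out Xist, Y-linked genes and symbols of gene models (Gm with digits, Rik or LOC); identifiers without any symbol were kept. It added up to 3 (or 2) called members of each list with the smallest adjusted p, and key genes whatever their result. In the interactions, which have 4 groups, the condition on overlap has no meaning and was not applied. The text gives part of the genes the rule took, and some of them are not reported here.

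The edgeR call was tested on simulated counts with 200 changed genes, for the comparisons named here only. Changed genes were drawn from those averaging at least 5 CPM, and all groups otherwise had the same mean. List tests, the overlap, the interactions and the Blimp1 comparisons were not simulated. For VAT Treg male versus female (16602 genes) 2.99% of genes changed 2-fold, 56.7% of those changed 4-fold and 75.8% of those changed 8-fold were called, with 6 unchanged genes called. For VAT tissue (16594 genes) these shares were 94% for 2-fold and 98.5% for 4-fold, for GP38-positive stroma (15851 genes) 1.49% and 26.9%, and for ILC2 (12768 genes) 0% and 35.8%.

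Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, only the groups compared, the replicate number as a block, and leaving out each library. After the data were seen, 2 more were added for T cells. The first left out 3 libraries picked by eye from single marker genes. As these were not the highest by summed markers of 8 lists of other cell types, the second left out the 4 highest by that sum; both are reported. Replicate pairs differed beyond sampling noise in every group, so none was merged. In GP38-positive male stroma the titles carry conflicting replicate numbers.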

Results

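The series holds RNA-seq of regulatory T cells (Treg) and their surroundings in mouse visceral adipose tissue (VAT), collected to study how Treg of this fat depot differ between males and females. It has 45 libraries in 22 groups, of 1 to 3 libraries each. Treg were sorted from VAT and spleen of both sexes through a fluorescent Foxp3 reporter, and reporter-negative CD4 T cells were sorted from VAT. Treg were also sorted from male mice whose Treg are labelled as carrying a conditional deletion of Blimp1, a transcriptional regulator encoded by Prdm1, and from Foxp3cre control mice. Further libraries came from whole VAT, subcutaneous fat, VAT adipocytes, stromal cells with or without GP38 (podoplanin), and VAT group 2 innate lymphoid cells (ILC2). Each library pooled 3 to 5 mice where the labels state a number. Between 4956080 and 61913009 reads per library were assigned to genes. In all 45 libraries Xist and the Y-linked genes matched the sex on the label, with at most 0.66 CPM of Xist in a male and at least 41.88 CPM in a female library.

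The first comparison asked how VAT Treg differ between the sexes. Male VAT Treg had far higher levels of genes that mark Treg resident in visceral fat. Il1rl1, which encodes the IL-33 receptor ST2, averaged 2199 ± 459.2 CPM (SD, n = 2) in males and 133.0 ± 22.67 CPM (SD, n = 2) in females, a log2 fold change of 4.05 (SE 0.27, edgeR adjusted p = 1.26e-07). Klrg1, a marker of terminally differentiated lymphocytes, was higher by 4.05 (SE 0.45, adjusted p = 5.05e-05). The chemokine receptor gene Ccr2 was higher by 2.71 (SE 0.33, adjusted p = 0.000118), and Gata3, a transcription factor gene, by 2.06 (SE 0.40, adjusted p = 0.00959). Il10, which encodes an anti-inflammatory cytokine, averaged 1072 CPM in males and 69.31 CPM in females, with a log2 fold change of 3.95 (adjusted p = 0.0413).

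Of 17340 genes tested, 280 were called at an adjusted p under 0.05, 125 of them higher and 155 lower in males. The largest rises by the fixed rule also included Ltb4r1, the leukotriene B4 receptor gene (4.44), Lpcat2 (4.36) and Hilpda (3.81). The largest falls included Ecel1 (-4.88), Scin (-3.90), St8sia1 (-3.42), Apol7e (-3.36) and Cdk5r1 (-3.27). Among 20 visceral fat Treg markers, 9 were called higher and none lower, and 13 were higher and 3 lower when adjusted over the list alone. The set test camera placed this list up (adjusted p = 1.42e-11, and adjusted p = 0.00337 with an estimated correlation). Fgl2 rose by 3.17 and the chemokine receptor gene Cxcr6 by 3.60. Mast cell and eosinophil markers summed to 431.9 and 258.1 CPM in male and 34.42 and 56.82 CPM in female VAT Treg, with their member Ccr3 up by 3.15. Of 20 immediate early and dissociation stress genes, 9 were higher and none lower, with Nr4a1 up by 3.10, Btg2 by 1.77 and Junb by 1.39 (camera adjusted p = 9.5e-12, and adjusted p = 0.0288 with an estimated correlation). Nr4a1 spread widely within males, at 4232 ± 3011 CPM (SD, n = 2). Over this list the CPM summed to 36870 and 25200 in male and 9404 and 10850 in female VAT Treg, and to 11050 and 12840 in male and 8197 and 7235 in female VAT CD4 T cells. In whole VAT they summed to between 957.7 and 986.6 in males and between 659.9 and 758.8 in females. Other cells of VAT did not follow this, with 22250 and 25220 CPM in male and 28530 and 23150 CPM in female ILC2, 11100 and 13360 against 17820 and 19540 CPM in adipocytes, 22560 and 18900 against 23090 and 22190 CPM in GP38-positive and 12440 and 17310 against 25430 and 24950 CPM in GP38-negative stroma.

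Genes of resting and lymphoid-homing T cells were lower in male VAT Treg. Of 15 members 4 were lower and 1 was higher, and 9 were lower and 1 was higher when adjusted over the list alone (camera adjusted p = 6.66e-09, and adjusted p = 0.0288 with an estimated correlation). Tcf7, a transcription factor of resting T cells, had a log2 fold change of -3.13 and the follicular homing receptor gene Cxcr5 -2.71. B cell markers summed to 3153 and 1914 CPM in female and 466.8 and 1167 CPM in male VAT Treg. Whether RNA of B cells adds to the genes lower in males was not tested. Interferon-stimulated genes were also lower, 6 of 20 called and 11 when adjusted over the list alone, with Isg15 at -2.17 and Ifih1 at -1.90 (camera adjusted p = 6.34e-13, and adjusted p = 0.00337 with an estimated correlation). The cell cycle list was placed down by camera (adjusted p = 1.23e-08), which was lost with an estimated correlation (adjusted p = 0.0773), and 1 of its 20 members, Ccna2, was called. Of the Treg core genes, Il2ra (1.55) and Ctla4 (1.44) were higher and Izumo1r (-2.02) was lower. Foxp3 (0.69, SE 0.68), Prdm1 (0.33, SE 0.36) and Pparg (2.79, SE 0.95, adjusted p = 0.265) did not pass the test. Macrophage markers were placed up by camera with 0 of 14 members called (adjusted p = 0.0195, and adjusted p = 0.687 with an estimated correlation), and turned down without VAT Treg female replicate 1 (adjusted p = 0.68).

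With only the 4 libraries compared, edgeR called 0 genes, 1677 had an unadjusted p under 0.05 and Il1rl1 had a log2 fold change of 4.09 (edgeR adjusted p = 0.0942), while DESeq2 on all T cell libraries called 547. The count was 94 without VAT Treg female replicate 1 and 107 without VAT Treg male replicate 1, and leaving out any of the 4 libraries ended the call of Il10, as all but male replicate 2 did for Gata3. The count was 450 without 3 T cell libraries picked by eye and 498 without the 4 highest in summed markers of other cell types, settings chosen after the data were seen and called the 3 and the 4 libraries below.

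**Figure D1:**
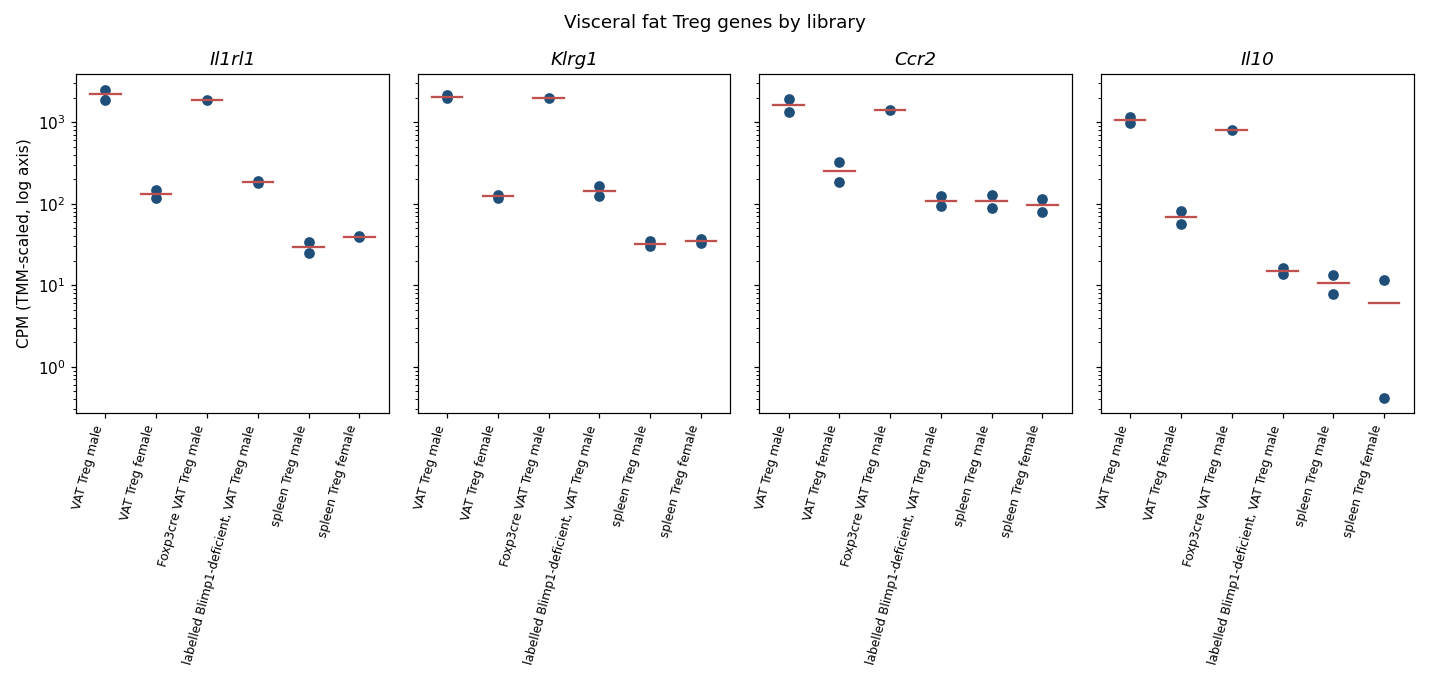
Levels of Il1rl1, Klrg1, Ccr2 and Il10 in 6 groups of sorted Treg, as CPM on a log axis; each point is a library and each red line a group mean. Male VAT Treg averaged 2199 CPM of Il1rl1 against 133.0 CPM in female VAT Treg, and the group labelled Blimp1-deficient averaged 186.2 CPM.

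In spleen Treg, the same contrast of the sexes gave 13 calls, 12 higher and 1 lower in males, of which Xist, Eif2s3y, Ddx3y, Uty and Kdm5d are the gene of X inactivation and Y-linked genes. The genes taken by the rule were Fndc10, Aurkb and Cpe, all with 0 counts in both female libraries. Fndc10 was at least 132-fold, the mitotic kinase gene Aurkb at least 127-fold and Cpe at least 105-fold higher in males, against a floor of 3 counts over the female group. These bounds cover counting error only, not the spread between pools. Cell cycle genes as a list summed to 683.8 and 623.8 CPM in male and 579.6 and 573.8 CPM in female spleen Treg. No list passed camera. The call count was 20 and 239 without spleen Treg female replicate 1 or 2, 24 without male replicate 2, 296 with DESeq2, 23 with no filter on low counts, 20 and 404 without the 3 and the 4 libraries, and 3 with the compared groups alone.

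The difference in sex effect between VAT and spleen was tested as an interaction, which called 92 genes, 37 with a larger VAT minus spleen difference in males and 55 with a smaller one. Il1rl1 (4.47, SE 0.36, edgeR adjusted p = 6.22e-06), Klrg1 (4.15), Cxcr6 (4.07), Areg, an epidermal growth factor family gene (5.35), and Ccr2 (2.54) were among the former. Tcf7 (-3.17), Cxcr5 (-2.82) and Izumo1r (-2.23) were among the latter. Immediate early and dissociation stress genes summed to 36870 and 25200 CPM in male and 9404 and 10850 CPM in female VAT Treg. In spleen Treg they summed to 3357 and 3271 CPM in males and 3625 and 3754 CPM in females. Whether handling of the tissues adds to this interaction was not tested. Visceral fat Treg markers were placed up by camera (adjusted p = 7.07e-12, and adjusted p = 0.00252 with an estimated correlation). Fibroblast and macrophage markers were placed up too, with none of 10 and 0 of 14 members called (adjusted p = 0.0129 and 0.0444), and neither held with an estimated correlation (adjusted p = 0.526 and 0.7). The count was 251 without spleen Treg female replicate 2, 48 without spleen Treg male replicate 1, 52 without VAT Treg female replicate 1, 59 without VAT Treg male replicate 1 and 40 with the compared groups alone. It was 426 with DESeq2, 166 with no filter on low counts, and 245 and 608 without the 3 and the 4 libraries.

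VAT CD4 T cells without the Foxp3 reporter differed between the sexes at 256 genes, 119 higher and 137 lower in males. Fgl2 (1.96, SE 0.27, edgeR adjusted p = 0.00245), Egr1 (2.86), the fractalkine receptor gene Cx3cr1 (2.95) and the cytotoxic granule gene Nkg7 (1.02) were higher, and Lef1, a transcription factor gene of resting T cells, was lower (-1.72). Il1rl1 had a log2 fold change of -0.14 (adjusted p = 0.939). Markers of other cells moved with sex here. Macrophage markers were higher for 12 of 14 members when adjusted over the list alone, with Adgre1 called over all genes, and macrophage, fibroblast and adipocyte markers were placed up by camera (adjusted p = 0.000438, 0.00158 and 0.00158), none of which held with an estimated correlation (adjusted p = 0.354, 0.312 and 0.312). Mast cell and eosinophil and endothelial markers were placed up and B cell markers down with no member called (camera adjusted p = 0.0167, 0.0318 and 0.00823), and none held (adjusted p = 0.312, 0.413 and 0.312). VAT CD4 male replicate 2 had the most of such markers among T cell libraries, with 12340 CPM over 8 lists. The count was 415 without that library, 588 without male replicate 1, 77 and 80 without either female library, 0 with the compared groups alone in edgeR (1100 at an unadjusted p under 0.05) and 1194 with DESeq2. It was 522 with no filter on low counts, and 445 and 665 without the 3 and the 4 libraries.

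The sex effect itself differed between Treg and CD4 T cells of VAT at 55 genes, 24 larger and 31 smaller in Treg. Il1rl1 (4.19, SE 0.36, edgeR adjusted p = 1.81e-05) and Klrg1 (3.06) were larger, and Cxcr3 (-2.33), Cxcr5 (-2.55), Tcf7 (-2.53) and Izumo1r (-1.79) were smaller. Camera also placed markers of other cells down in this interaction, with no member called: adipocyte (adjusted p = 0.00393), fibroblast (0.0077), macrophage and endothelial markers (0.0475 each) and MHC class II genes (0.0195). None of these held with an estimated correlation (adjusted p = 0.332, 0.417, 0.622, 0.542 and 0.542). Without VAT CD4 male replicate 2 the macrophage and MHC class II lists turned up, as the macrophage list did without VAT Treg female replicate 2. Without the 3 and without the 4 libraries, the macrophage, MHC class II, fibroblast and endothelial lists all turned up, as given below. With the compared groups alone edgeR called 0 genes, with 1091 at an unadjusted p under 0.05, and DESeq2 called 391, no filter on low counts gave 120, and leaving out the 3 and the 4 libraries gave 209 and 295. The count was 211 and 142 without VAT CD4 male replicate 2 or 1, 15 without VAT CD4 female replicate 2, 25 without VAT Treg female replicate 1 and 22 without VAT Treg male replicate 1.

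VAT and spleen Treg were then compared within each sex. In males 1137 genes were called, 608 higher in VAT and 529 lower. Il1rl1 was higher in VAT by 6.22 (SE 0.30, edgeR adjusted p = 1.65e-09), Klrg1 by 5.98, Il10 by 6.66, Areg by 8.44, Gata3 by 3.61, Ccr2 by 3.92, Ctla4 by 3.10 and Prdm1 by 1.44. The cytokine genes Il5 and Csf2 had 0 counts in spleen and were at least 764-fold and 479-fold higher in VAT. Tcf7 (-3.27), Cxcr5 (-3.95) and Izumo1r (-2.85) were lower in VAT. Foxp3 (1.66, adjusted p = 0.205) and Pparg (3.17, adjusted p = 0.0578) did not pass. Of 20 visceral fat Treg markers 15 were higher and 2 lower (camera adjusted p = 7.42e-10, and adjusted p = 0.00482 with an estimated correlation).

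Markers of the surrounding tissue separated the same libraries. Fibroblast markers were called higher in male VAT Treg than in spleen Treg for 8 of 10 members, among them Lum, Dcn and Col1a2, and B cell markers were called lower for 7 of 10, among them Ighm (-2.46) and Cd79a (-4.19). The largest rises by rule were matrix genes and Frmd5: Col4a2, Col6a2, Bgn, Fbln2 and Col6a1 all had 0 counts in spleen. The largest falls were immunoglobulin variable genes such as Igkv8-24 and Igkv3-4, whose reads near-identical copies can share. Immediate early and dissociation stress genes summed to 36870 and 25200 CPM in male VAT Treg and to 3357 and 3271 CPM in male spleen Treg. Whether handling of the tissues adds to the genes called here was not tested. The count was 405 and 565 without spleen Treg male replicate 1 or 2 and 497 without VAT Treg male replicate 1, 2111 with DESeq2 and 2086 without the 4 libraries.

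In females VAT and spleen Treg differed at 296 genes, 247 higher in VAT and 49 lower. Il1rl1 was higher by 1.75 (SE 0.25, edgeR adjusted p = 0.00133), Klrg1 by 1.83, Cxcr6 by 1.53, Ccr2 by 1.38 and Ctla4 by 1.39, and 5 of 20 visceral fat Treg markers were called. Camera placed that list up (adjusted p = 0.000954), which was lost with an estimated correlation (adjusted p = 0.0998). Immediate early and dissociation stress genes summed to 9404 and 10850 CPM in female VAT Treg and to 3625 and 3754 CPM in female spleen Treg. Fibroblast (4 of 10) and endothelial (3 of 11) markers were called higher in VAT, and VAT Treg female replicate 2 held 8171 CPM of markers of other cells. The count was 82 without that library, 78 and 529 without spleen Treg female replicate 1 or 2, 1 with the compared groups alone, 1301 with DESeq2, 575 with no filter on low counts and 817 without the 4 libraries.

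Treg labelled Blimp1-deficient were compared with Foxp3cre Treg from male VAT. Prdm1, the targeted gene, was not lower in the libraries so labelled: they had 121.1 and 147.8 CPM, against 73.09 CPM in the single Foxp3cre VAT library, and in spleen 41.2 and 60.76 CPM against 16.34 and 24.99 CPM. A count over the whole gene includes exons outside a deleted part, so it does not check the label. Visceral fat Treg genes were lower in the libraries labelled Blimp1-deficient. Il1rl1 had a log2 fold change of -3.32 (SE 0.29, edgeR adjusted p = 7.25e-06), Klrg1 -3.77, Ccr2 -3.67, Fgl2 -3.90, Cxcr6 -2.48 and Il10 -5.74 (SE 1.09, adjusted p = 0.015), whose call ended without either labelled library. Anxa1 (-4.15), Ccr3 (-5.40) and Camk2b (-4.91) were among the largest falls, and Adra2c, with 0 counts in the labelled group, was at least 1200-fold lower.

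In all, 142 genes were called, 77 higher and 65 lower. Cxcr5 (3.37) and Tcf7 (2.53) were higher. Ccr6, a chemokine receptor gene, Cd160 and the interferon-stimulated gene Ifi44 had 0 counts in the Foxp3cre library and were at least 767-fold, 209-fold and 178-fold higher. With a single control library, these bounds cover counting error only. Of 20 visceral fat Treg markers 6 were lower, and 11 were lower and 1 higher when adjusted over the list alone (camera adjusted p = 6.99e-07, and adjusted p = 0.0177 with an estimated correlation). Cell cycle genes such as Ccna2 (2.37) and Mcm5 (1.56) were placed up (adjusted p = 3.24e-12, and adjusted p = 0.0336 with an estimated correlation), as were interferon-stimulated genes such as Oas1a (2.18) (adjusted p = 6.99e-07, and adjusted p = 0.0336 with an estimated correlation). Foxp3 (-0.50), Gata3 (-1.71, adjusted p = 0.101) and Pparg (-3.26, adjusted p = 0.242) did not pass. Immediate early and dissociation stress genes were lower as well. Of 20 members 4 were lower, and 11 when adjusted over the list alone, with Nr4a1 at -2.68, Fosb at -3.52 and Junb at -1.22 (camera adjusted p = 1.13e-07, lost with an estimated correlation at adjusted p = 0.0803). The list summed to 27270 CPM in the Foxp3cre library and to 10250 and 9614 CPM in the labelled libraries. Mast cell and eosinophil markers summed to 286.9 CPM in the Foxp3cre library and to 22.04 and 24.4 CPM in the labelled libraries. Visceral fat Treg markers summed to 13040 CPM in the Foxp3cre VAT library and to 1176 and 1224 CPM in Foxp3cre spleen Treg. Fibroblast markers summed to 861.2 CPM against 1.932 and 2.924 CPM. By these sums the Foxp3cre VAT library resembled Treg of VAT rather than of spleen. Fibroblast, endothelial and adipocyte markers were placed down with no member called (camera adjusted p = 0.000521, 0.00835 and 0.0155), and none held with an estimated correlation (adjusted p = 0.283, 0.489 and 0.419). B cell markers were placed up with no member called (adjusted p = 0.0321, and adjusted p = 0.489 with an estimated correlation). The control is a single library, whose spread is taken from the other groups, and its source text names spleen where its title and tissue label name VAT; the count was 51 and 44 without either labelled library. It was 615 with the compared groups alone, 567 with DESeq2, 269 with no filter on low counts, and 351 and 466 without the 3 and the 4 libraries.

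The genes higher in male VAT Treg overlapped those lower in the libraries labelled Blimp1-deficient. The 2 comparisons use different libraries. Of 125 and 65 such genes, 48 were shared, where independent lists among 17340 genes would share 0.469 (Fisher's exact test, two-sided, p = 8.05e-93). They included Il1rl1, Klrg1, Ccr2, Il10, Areg, Fgl2, Cxcr6, Ctla4, Il2ra, Anxa1, Il10ra, Cd69, Vim, S100a4, S100a6 and Lgals1, and the immediate early and stress genes Nr4a1, Fosb, Junb and Ier2, with Csrnp1, Nfkbiz and Nfkbid. The summed immediate early and dissociation stress genes differed in both comparisons. In the mirror direction, 42 genes were lower in males and higher in the labelled libraries, against 0.688 for independent lists, and no gene was called in a like direction in both. Summed B cell markers went the same way, with 466.8 and 1167 CPM in male against 3153 and 1914 CPM in female VAT Treg. They stood at 1028 and 1284 CPM in the labelled libraries against 315.1 CPM in the Foxp3cre library. Whether RNA of B cells adds to these 42 genes was not tested. Both comparisons come from a fit with a common spread, and genes are not independent replicates. With the compared groups alone the overlap was 0, since no gene was called between the sexes, and it was 21 and 17 without either labelled library. It was 95 with DESeq2, 76 with no filter on low counts, and 100 and 114 without the 3 and the 4 libraries.

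**Figure D2:**
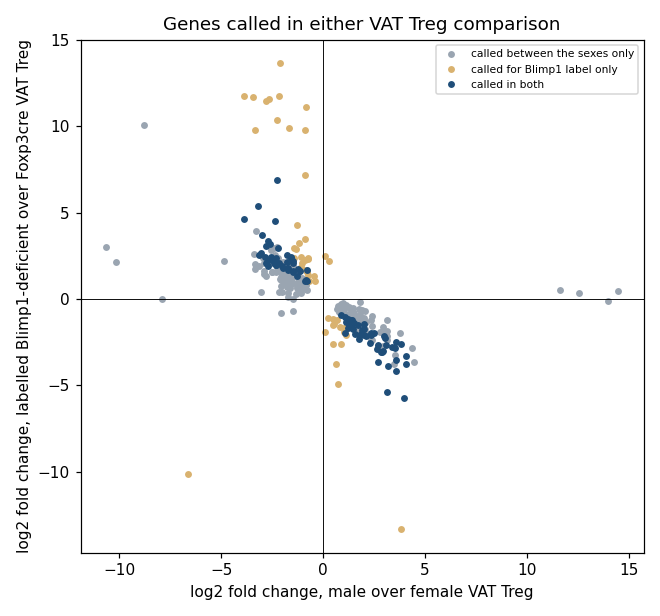
Log2 fold changes of male over female VAT Treg (x axis) and of VAT Treg labelled Blimp1-deficient over Foxp3cre VAT Treg (y axis), for genes called in either comparison; each point is a gene. The genes called in both comprise 48 at the lower right and 42 at the upper left.

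In spleen the libraries labelled Blimp1-deficient differed from Foxp3cre at 55 genes, 18 higher and 37 lower. The heat shock genes Hsph1 (3.33, SE 0.48, edgeR adjusted p = 0.00239), Dnaja4 (3.04) and Dnajb1 (1.91) were higher, and Ccr2 (-2.51) and Fgl2 (-1.67) were lower. Of 10 B cell markers 6 were called lower, and all 10 when adjusted over the list alone, with Cd79a at -7.35 and Ms4a1 at -8.04 (camera adjusted p = 7.44e-17, and adjusted p = 0.0467 with an estimated correlation). The control libraries differed: B cell markers summed to 2750 and 6576 CPM and MHC class II genes to 2805 and 7628 CPM in Foxp3cre spleen replicates 1 and 2, against 1362 and 1376 CPM and 942 and 827.9 CPM in the labelled libraries. Replicate 2 held 8295 CPM of markers of other cells, and Foxp3 stood at 30.69 CPM in the lower and 144.9 CPM in the higher of both. Neutrophil and monocyte, CD8 and NK cell, macrophage and MHC class II lists were also placed down (camera adjusted p = 5.65e-07, 6.04e-07, 0.000362 and 3.65e-08), and none held with an estimated correlation (adjusted p = 0.0855, 0.0533, 0.698 and 0.308). The count was 1 without the labelled replicate 1, 33 without replicate 2, 18 without Foxp3cre replicate 2, 93 without its replicate 1, 315 with DESeq2, 147 with no filter on low counts and 8 with the compared groups alone.

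Whole VAT was compared between the sexes, as epididymal fat of males against periovarian fat of females, so that sex and fat pad go together. Macrophage genes were higher in males, 11 of 14 markers, with Itgax at 118.6 ± 16.40 CPM (SD, n = 3) against 7.791 ± 0.6483 CPM (SD, n = 3), a log2 fold change of 3.93 (SE 0.25, edgeR adjusted p = 5.14e-07), Cd68 at 2.65 and Adgre1 at 2.30. Camera placed them up (adjusted p = 7.48e-16), which was lost with an estimated correlation (adjusted p = 0.133). The chemokine gene Ccl2 was higher by 1.84 (adjusted p = 0.00148), the elastase gene Mmp12 by 5.18 and osteopontin, Spp1, by 4.59. Cell cycle genes were higher for 14 of 20 members, among them Mki67 (1.75), Top2a (1.62) and Pcna (0.77) (camera adjusted p = 1.06e-12, and adjusted p = 0.0135 with an estimated correlation).

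HOX and patterning genes were lower in male VAT for 15 of 27 members, led by Hoxa10 (-8.98, SE 0.32, edgeR adjusted p = 1.48e-09; chromosome 6, 52231197 to 52240854, GRCm38.p6), Hoxc10 (-7.21) and Hoxa9 (-6.86) (camera adjusted p = 7.98e-19, and adjusted p = 0.00883 with an estimated correlation). The estrogen receptor gene Esr1 was lower (-1.29, edgeR adjusted p = 5.86e-05), as were Cfd (-1.14), Retn (-0.91), Gpam (-1.28) and the steroid enzyme gene Akr1c14 (-2.25). Adipocyte markers were lower too, for 4 of 10 members (camera adjusted p = 0.0412, lost with an estimated correlation at adjusted p = 0.696). Hsd11b1 (0.80) and Sult1e1, a sulfotransferase gene acting on estrogens (9.63), were higher. Of the key genes, Il33 (-0.76, adjusted p = 0.126), Il6 (0.85), Il1b (1.29) and Tnf (adjusted p = 0.0532) did not pass. In all 2216 genes were called, 1419 higher and 797 lower, and the count was 1265 without VAT tissue male replicate 1 and 1398 without its replicate 3.

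Subcutaneous fat differed between the sexes at 2795 genes, 1200 higher and 1595 lower in males. Respiratory chain genes were higher for 19 of 22 members, such as Sdha (0.73) (camera adjusted p = 2.06e-13, lost with an estimated correlation at adjusted p = 0.366). Hsd11b1 (2.99, SE 0.15, edgeR adjusted p = 8.02e-08), the lipogenic genes Acacb (2.56) and Srebf1 (1.37), Plin5 (1.84) and the complement gene C7 (4.73) were higher, and Esr1 (-0.76) and Il33 (-1.36, adjusted p = 0.0425) were lower. Adipocyte markers were higher for 4 of 10 members (camera adjusted p = 0.0438, lost with an estimated correlation at adjusted p = 0.617). A gene known here by NCBI identifier 100628579 alone was also among the largest rises (3.68). Mammary and general epithelial markers were lower in males for 10 of 11 members, such as Cldn3 (-9.12) and Cdh1 (-8.38) (camera adjusted p = 1.06e-18, and adjusted p = 0.0532 with an estimated correlation). They summed to 235.2 and 577.9 CPM in female and 0.1679 and 2.906 CPM in male libraries. Sex and the epithelial RNA in the pad thus go together in this comparison. The count was 1126 with the compared groups alone and 1388 and 1778 without female replicate 2 or male replicate 1.

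The sex effect differed between the depots at 2714 genes, 1670 more positive and 1044 more negative in VAT. Itgax (4.22, SE 0.40, edgeR adjusted p = 6.77e-05), Cd68 (2.41), Mki67 (2.50) and Ccl2 (2.09) were more positive in VAT, and Hoxa10 (-9.27), Hsd11b1 (-2.19), Cfd (-2.30) and Plin5 (-1.96) were more negative. Cell markers differed too, with macrophage (8 of 14) and mammary and general epithelial markers (7 of 11) more positive and adipocyte markers (5 of 10) more negative in VAT (camera adjusted p = 1.08e-07, 3.28e-08 and 0.000774), and none held with an estimated correlation (adjusted p = 0.245, 0.139 and 0.268). The epithelial markers summed to 3.317 to 15.04 CPM in female and 4.478 to 8.11 CPM in male VAT. Their difference thus came from female subcutaneous fat, at 235.2 and 577.9 CPM. The count was 1706 without subcutaneous tissue female replicate 2.

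Adipocytes of VAT differed between the sexes at 5976 genes, 2453 higher and 3523 lower in males. Lipogenic genes were higher for 15 of 19 members and lower for 1, with Srebf1 called (SE 0.19, edgeR adjusted p = 6.13e-05), Dgat2 at 1.57 and Scd1 at 1.56 (camera adjusted p = 8.54e-07, lost with an estimated correlation at adjusted p = 0.285). Of 10 adipocyte markers 6 were higher (camera adjusted p = 0.00193, lost with an estimated correlation at adjusted p = 0.312). Plin1 (1.06), Lipe (0.92), the leptin gene Lep (0.91) and Hsd11b1 (2.79) were higher. Il33 (-2.77, adjusted p = 0.000616) and the cytokine gene Il6 (-3.89, adjusted p = 0.000233) were lower. Fibroblast markers fell in the same libraries, with a median log2 fold change of -2.48. These libraries therefore do not tell which cells the Il33 and Il6 came from. Ucp1, the uncoupling protein of brown fat, had 0 counts in males and was at least 159-fold lower. Hoxa10 (-5.25) and Hoxc10 (-4.72) were lower. Ccl2 (0.40), Esr1 (-0.41), Il1b (-0.93) and Tnf (-0.98) did not pass.

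Markers of several other cell types were lower in the male adipocyte libraries. Of 11 endothelial markers 9 were lower, such as Cldn5 (-1.97) and Emcn (-2.16), of 10 fibroblast markers 9 were lower, such as Pdgfra (-3.24) and Lum (-3.60), and of 12 MHC class II genes 11 were lower, such as H2-Aa (-1.80). Camera placed these down (adjusted p = 8.54e-07, 8.54e-07 and 3.12e-05), each lost with an estimated correlation (adjusted p = 0.257 for each). Of 10 B cell markers 5 were lower, such as Cd79a (-3.39), and Ighm was higher (0.97), with a sum of 638.8 and 647.3 CPM in females and of 1199 and 980.6 CPM in males. Neutrophil and monocyte markers, 5 of them measured, summed to 7.869 and 5.914 CPM in females and to 10.74 and 4.295 CPM in males, with S100a8 higher (2.24) and S100a9 lower (-2.82). VAT adipocytes female replicate 1 had the lowest total of the series, 4956080 reads.

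GP38-positive stroma differed between the sexes at 55 genes, 35 higher and 20 lower in males. The angiotensinogen gene Agt averaged 474.0 ± 41.24 CPM (SD, n = 2) in males and 5.253 ± 2.154 CPM (SD, n = 2) in females, a log2 fold change of 6.49 (SE 0.44, edgeR adjusted p = 0.00621). Haptoglobin, Hp (5.92), S1pr3 (3.62), Clic5 (3.96), the collagen cross-linking gene Lox (1.76) and Timp3 (1.37) were higher, and Lrrn1 and Dok7, with 0 counts in females, were at least 1890-fold and 969-fold higher. Myoc (-6.24), Dkk3, Gucy1a1 (-3.80), Igfbp3 (-3.50), H2-Q7 (-3.37), Il4ra (-3.09), Icam1 (-1.69) and Lpl (-1.54) were lower. Il33 (-0.53, SE 1.73), Ccl2 (0.82, SE 0.58), Il6 (0.01) and Esr1 (-2.15, adjusted p = 0.328) did not pass. The Esr1 levels did not overlap, at 53.93 and 44.05 CPM in females and 10.31 and 11.73 CPM in males. A simulation of this comparison recovered 26.9% of genes changed 4-fold, so a gene that did not pass is not thereby unchanged. Adipocyte markers were placed up with none of 10 called (camera adjusted p = 0.00251, and adjusted p = 0.782 with an estimated correlation). Leaving out single libraries gave 10 and 4 calls without either female library and 6 and 4 without either male library, DESeq2 called 545, the compared groups alone gave 280 and no filter on low counts gave 92.

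GP38-negative stroma differed at 146 genes, 35 higher and 111 lower in males. Esr1 (-4.69, SE 0.66, edgeR adjusted p = 0.0354), Lum (-2.46), Acta2 (-1.86) and Ccl11 (-1.67) were lower, and Scd1 (2.32), Lox (1.56) and Hsd11b1 (1.04) were higher. Of 10 T cell markers, Thy1 was called higher, and 3 were higher when adjusted over the list alone (camera adjusted p = 0.000213, and adjusted p = 0.3 with an estimated correlation). Of 10 mural cell markers 1 was lower, and 7 when adjusted over the list alone (camera adjusted p = 1.44e-06, and adjusted p = 0.136 with an estimated correlation). Adipocyte markers were placed up with none of 10 called (camera adjusted p = 0.0226, and adjusted p = 0.58 with an estimated correlation), and they summed to 13320 and 15960 CPM in males and 10760 and 9160 CPM in females. Neutrophil and monocyte markers were placed up and skeletal muscle markers down with no member called (adjusted p = 0.0118 and 0.027), and immediate early and dissociation stress genes were also placed down with none of 20 called (adjusted p = 0.000437). None of these held with an estimated correlation (adjusted p = 0.3, 0.495 and 0.515). The count was 5 without female replicate 1, 21 without female replicate 2, 814 and 522 without either male library, 1 with the compared groups alone, 1345 with DESeq2 and 221 with no filter on low counts.

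VAT ILC2, which share Il1rl1, Klrg1 and Gata3 with VAT Treg, differed between the sexes at 5 genes: Xist and the Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d. Il1rl1 averaged 1799 ± 460.5 CPM (SD, n = 2) in males and 1563 ± 521.4 CPM (SD, n = 2) in females, a log2 fold change of 0.20 (SE 0.42). Klrg1 (0.55, SE 0.48), Ccr2 (0.10, SE 0.38), Pparg (-0.05, SE 0.43), Gata3 (-0.16, SE 0.39) and Tcf7 (0.45, SE 0.43) did not pass. No list passed camera. The count was 32 and 10 without ILC2 female replicate 1 or 2, 24 and 41 without male replicate 1 or 2, 37 with DESeq2 and 19 with no filter on low counts. Same-numbered libraries of both sexes deviated alike from their group means (correlation 0.355). With the replicate number as a block the count was higher, as given below, so calls beyond sex-linked genes are not excluded. A simulation of this comparison recovered 35.8% of genes changed 4-fold and none changed 2-fold, among genes averaging at least 5 CPM. The difference in sex effect between ILC2 and Treg was not tested, since the libraries came from different kits and fits.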

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

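Tests of explanations in this part were chosen after the result was seen. The difference between the sexes itself differed between groups in 3 interaction tests of edgeR: at 92 genes between VAT and spleen Treg, at 55 genes between Treg and CD4 T cells of VAT, and at 2714 genes between VAT and subcutaneous fat.

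Visceral fat Treg markers were higher in male than in female VAT Treg. Scaled to the summed Il5 and Il13 of a male VAT Treg library, RNA of male ILC2 would bring up to 6.02% of its Il1rl1, but the genes differ: Il5 alone gives 1.79% and 2.45% in the 2 libraries, and Il13 alone, low in ILC2 at 20.54 CPM, gives 214% and 116%. Il5, abundant in male ILC2 at 1011 CPM, stood at 24.1 and 26.69 CPM, and with the ILC2 library lowest in Il5 per Il1rl1 gave 4.38% and 6.01%. The ILC2 libraries were made with another kit than the Treg libraries. Only if both kits give a like ratio of Il5 to Il1rl1 does this argue against ILC2 like those sorted here as the main source. Without the 4 T cell libraries highest in summed markers of other cell types, the median fitted log2 fold change of the list was 2.99 against 2.38. Of the 4, only VAT Treg female replicate 2 enters this contrast. The list summed to 3663 and 3869 CPM in female and 16830 and 15280 CPM in male VAT Treg, so leaving it out could not end the difference. The setting shows only that the difference does not rest on that library. VAT Treg male replicate 2, with 7279 CPM of markers of other cells, stayed in. Summed early genes were higher in male Treg and CD4 T cells of VAT but not in male ILC2, adipocytes or stroma. They were also higher in males in whole VAT, where no cells were sorted, so dissociation does not account for that difference. Whole VAT mixes cell types, and macrophage markers were higher there in males. Its sums of early genes were 957.7 to 986.6 CPM in males and 659.9 to 758.8 CPM in females, while VAT adipocyte libraries held 11100 to 19540 CPM. Whole VAT therefore does not tell whether dissociation differed between the Treg libraries. Differences of dissociation between the Treg libraries and biological sex stay open and were not tested. RNA of cells other than ILC2 stays open as well.

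Most lists of stromal, vascular and leukocyte markers were placed higher by their medians in female than in male adipocytes, while Ighm and S100a8 were higher in males and summed neutrophil and monocyte markers overlapped. A lower share of adipocytes alone would raise all other cell types alike. The medians of 8 such lists lay between -1.01 for macrophages and -3.46 for mast cells and eosinophils. They lay further apart than members shuffled over the lists gave (permutation test, one-sided, p = 0.00626, and p = 0.00957 over 9 lists with neutrophil and monocyte markers added). Some members stood near 0 CPM with no TMM scaling, such as Cd3e at 0.6014 in females and 0 in males, and Cd4 at 1.647 and 0.1534. Fold changes of such genes are uncertain, so medians may also lie apart for that reason. The shuffle treats genes as independent, though markers of a cell type can move together. Its p measures spread between genes, not between pools, so it does not decide whether a lower share is the whole cause. Female replicate 2, with 16738869 reads, held 3175 CPM of fibroblast and 3546 CPM of endothelial markers. The male libraries held 1445 and 1206 CPM, and 905.3 and 873.5 CPM. Its B cell and its neutrophil and monocyte sums were not above both males. For the raised lists, this argues against the low total of female replicate 1 as the cause. A lower share of adipocytes, other mixtures of cells and biological sex stay open.

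B cell markers were lower in spleen Treg labelled Blimp1-deficient, for 10 of 10 members adjusted over the list alone; they summed to 1362 and 1376 CPM there, to 2750 and 6576 CPM in Foxp3cre replicates 1 and 2, and to 5019 to 5690 CPM in the other spleen Treg libraries. RNA of B cells in the Foxp3cre spleen Treg libraries is a candidate source, which sorting on the Foxp3 reporter should remove. These values are of the genes that define the pattern and so decide nothing, and an effect of the deletion cannot be told apart from it.

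Splitting the 6 VAT tissue libraries in all 10 ways into groups of 3, the real split called 2216 genes and the highest of the others 0 in edgeR, so that 1 split reached the real count. These splits are too few for a share under 0.05.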

How the results depend on the processing

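Leaving out 3 T cell libraries picked by eye, or the 4 highest in summed markers of other cell types, was chosen after the data were seen; the other settings were planned. Of named genes and lists, tested again in each setting, genes were alike in 4293 cases and no longer passed in 873, with 0 reversed; lists were alike in 1301, no longer passed in 149 and turned in 12. Where counts moved, the cause was not tested; leaving out libraries also makes groups smaller, and a lone library is then taken to vary like the other groups.

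With DESeq2 the counts were 547 for VAT Treg, 296 for spleen Treg, 1194 for VAT CD4, 2111 for VAT versus spleen in males, 1301 in females, 426 for the interaction with tissue, 391 with cell type, 567 and 315 for Blimp1 in VAT and spleen, 545 and 1345 for GP38-positive and GP38-negative stroma, 37 for ILC2 and 95 for the overlap. With no filter on low counts they were 23 for spleen Treg, 522 for VAT CD4, 575 for VAT versus spleen in females, 166 and 120 for the interactions with tissue and cell type, 269 and 147 for Blimp1 in VAT and spleen, 92 and 221 for GP38-positive and GP38-negative stroma, 19 for ILC2 and 76 for the overlap. With only the groups compared, edgeR called 0 for VAT Treg (1677 at an unadjusted p under 0.05), 3 for spleen Treg, 0 for VAT CD4 (1100), 1 for VAT versus spleen in females, 40 and 0 (1091) for the interactions, 615 and 8 for Blimp1 in VAT and spleen, 1126 for subcutaneous fat, 280 and 1 for the stroma and 0 for the overlap. The labels give libraries of different groups only a shared replicate number. Deviations of same-numbered libraries from their group means correlated across genes between -0.08 (VAT CD4 of both sexes) and 0.355 (ILC2 of both sexes), and in VAT tissue, with 3 pairs, at 0.01, 0.065 and -0.069; a shared day or batch was not excluded. With the replicate block the counts were 84 for the interaction with cell type, 14 and 33 for the stroma and 9 for ILC2.

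Without the 3 libraries the counts were 450 for VAT Treg, 20 for spleen Treg, 445 for VAT CD4, 245 and 209 for the interactions, 351 for Blimp1 in VAT and 100 for the overlap. Without the 4 they were 498, 404 and 665 for VAT Treg, spleen Treg and VAT CD4, 2086 and 817 for VAT versus spleen in males and females, 608 and 295 for the interactions, 466 for Blimp1 in VAT and 114 for the overlap.

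Leaving out each library gave 94 to 207 for VAT Treg, 10 to 239 for spleen Treg, 77 to 588 for VAT CD4, 405 to 789 for VAT versus spleen in males, 78 to 529 in females, 48 to 251 and 15 to 211 for the interactions, 44 to 51 and 1 to 93 for Blimp1 in VAT and spleen, 1265 to 1834 for VAT tissue, 1388 to 2794 for subcutaneous fat, 1706 to 2772 for the depots, 4082 to 4619 for adipocytes, 4 to 10 and 5 to 814 for the stroma, 10 to 41 for ILC2 and 17 to 45 for the overlap.

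Lists turned, with camera adjusted p, in the interaction with cell type: MHC class II presentation at 0.473 without VAT CD4 male replicate 2 (5.27e-06 to 0.473 over single libraries), 0.101 without the 3 and 0.168 without the 4; macrophage markers at 0.637 without that library, 0.876 without VAT Treg female replicate 2 (0.00031 to 0.876), 0.011 without the 3 and 0.0334 without the 4; fibroblast markers at 0.613 and 0.615, and endothelial markers at 0.436 and 0.47, without the 3 and the 4. Macrophage markers also turned between the sexes in VAT Treg, at 0.68 without female replicate 1 (2.49e-06 to 0.959). The cause was not tested.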

Other observations

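The test of the hypothesis below was chosen after the result was seen. Several gene groups outside the account above moved in fat. In VAT tissue, inflammatory cytokines and chemokines were higher in males for 10 of 28 members and lower for 1 (camera adjusted p = 1.78e-05, and adjusted p = 0.0685 with an estimated correlation), and MHC class II genes were higher for 6 of 12 (adjusted p = 3.33e-05, and adjusted p = 0.222 with an estimated correlation). In subcutaneous fat, skeletal muscle markers were lower in males for 5 of 10 members (camera adjusted p = 0.00231, and adjusted p = 0.5 with an estimated correlation) and mesothelial markers for 5 of 11 (adjusted p = 2.75e-05, and adjusted p = 0.461 with an estimated correlation). In adipocytes, interferon-stimulated genes were lower in males for 13 of 20 members (camera adjusted p = 1.37e-05, and adjusted p = 0.293 with an estimated correlation).

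A hypothesis is that genes higher in male VAT Treg may depend on Blimp1. Of them, 48 were lower in the libraries labelled Blimp1-deficient, where independent lists would share 0.469, and none was higher. That goes with the hypothesis, but the hypothesis was found on the same data, so the overlap is no separate test of it. Shared genes such as Il1rl1, Klrg1, Il10 and Areg were also higher in VAT than in spleen Treg of males. They are thus not particular to the Blimp1 comparison. The overlap rests on a label that counts over the whole Prdm1 gene do not check, and on a single control library. Both comparisons also share an estimate of spread. Other differences between the mice stay open. A difference in dissociation also stays open, as summed immediate early and stress genes were higher in male VAT Treg and in the Foxp3cre library alike. They were not higher in male ILC2, adipocytes or stroma of VAT. In whole VAT, where no cells were sorted, they were higher in males, which dissociation does not account for. Whole VAT mixes cell types and summed to at most 986.6 CPM, so it does not tell whether dissociation differed between the Treg libraries.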
